A study of Mus musculus with 28 samples.

How the data were processed

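RNA from mouse hippocampus was labelled with biotin after whole-transcript target preparation and hybridised to Affymetrix arrays, per the labels' protocols. There were 28 arrays in 4 groups of 7, and the groups were taken from the sample titles. The deposited value table held log2 intensities that the authors had made with RMA, per the submitters' processing notes; the version and options are not given in the sources used here. RMA corrects background, normalizes probe intensities by quantiles and summarizes them per row, so array medians differ little by construction and a shift shared by most genes would be reduced. The table had 41345 rows. A second table by the authors held the log2 means, SDs and fold differences of 23410 rows with a gene symbol, with unadjusted p-values for each treatment against PBS and for the 4 groups, per the file headers. Its means and SDs equalled those of the value table within 1e-08, and its p-values equalled equal-variance tests of it within 1.24e-07, so both tables hold the same measurements. The depth of an array is its signal over background, which the files do not state.

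Gene symbols were taken from the authors' table. Of these, 26 had been turned into dates or numbers and were restored from a combined name column. The 22256 distinct symbols were matched to the RefSeq genes of GRCm38.p6, used for names only: 20597 were current symbols and 972 matched a synonym. The files name no genome build, so no coordinates are given. The remaining 17935 rows without a symbol entered 1 alternative. Rows with a mean over all arrays under the 30th percentile of named rows, 4.68 on the log2 scale, were left out, and a gene with several rows, as 898 had, was represented by the row with the highest mean. Whether the rows of a gene agreed was examined only for genes named in the text, and among these the rows of C1qb and Syne1 disagreed in sign.

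Tests were fixed before the data were examined, except where stated here or in the closing section. Each gene was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 28 arrays and eBayes moderation, and p-values were adjusted by Benjamini-Hochberg over 15781 genes with a threshold of 0.05. The 7 comparisons were each plasma against PBS, the 3 pairs of plasma groups, and the mean of the plasma groups against PBS, with a moderated F-test over the groups. Differences are on the log2 scale and SE is the moderated standard error. The 30 gene lists, 16 of pathways and 14 of cell or tissue markers, were fixed in advance and tested with camera at a preset correlation of 0.01 and at an estimated correlation, with adjustment over the lists. The mean of the immediate early genes per array was tested by an exact two-sided permutation over the 3432 splits of 14 arrays, with a smallest p of 0.000583, and adjusted over 4 comparisons. The same test of every list, the covariates for choroid plexus and cortex markers, the fit without 2 arrays and the adjustment of the authors' p-values were chosen after the data had been seen. Per1 belongs to the immediate early, clock and glucocorticoid lists, and Rorb to the clock list and the cortex markers.

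The genes named are those of a rule fixed in advance: the 10 largest changes in each direction among genes that passed, the smallest unadjusted p where fewer than 5 passed, 4 members of each list that camera called, the 10 smallest p of the F-test, and 14 genes of neuronal activity, ageing and glia chosen beforehand. The text gives part of them, and that part was chosen after their values had been seen. Groups were compared with simulated unchanged groups where they shared the PBS arrays, 100 splits of the arrays, the real one included, were counted for each result, and each array was left out in turn. Alternatives were no filter, a filter at the 50th percentile, the mean over a gene's rows, every row, renewed quantile normalization, centring on the array median, the authors' means and SDs, a trended and robust fit, array weights, the arrays of 2 groups alone, a replicate block, and other thresholds.

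The gene test was tested on simulated data. With 200 of 15781 genes changed between simulated cord plasma and PBS arrays, limma called 46% of those changed by 0.25 on the log2 scale, 92% at 0.5 and 100% at 0.75 and at 1, with 9 false calls among 178. The simulated noise was independent between genes, and 200 changed genes ease the adjusted threshold. These shares therefore need not hold for the real arrays.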

Results

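Hippocampi of aged mice were profiled on whole-transcript microarrays after the animals had received 6 intravenous injections of human plasma or of phosphate-buffered saline (PBS), the vehicle. The mice were of the NSG strain, an immunodeficient background that lacks mature lymphocytes, and had a mean age of 14 months. The 28 arrays formed 4 groups of 7, given PBS, plasma from umbilical cord blood, plasma from young donors or plasma from old donors. The question was whether human plasma, and the age of its donors, altered gene expression in the aged hippocampus. The deposited values were log2 intensities for 41345 rows, of which 23410 carried a gene symbol, and 15781 genes were tested. The median log2 value of an array ran from 4.96 to 5.09, and the correlation of 2 arrays across genes from 0.976 to 0.995. The labels did not say that each array came from a separate mouse, so p-values measure the spread between these samples, and 7 arrays per group limit the precision.

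Cord plasma was compared with PBS first. Immediate early genes, which neurons transcribe within minutes of activity, rose as a group with cord plasma. The mean log2 value over the 31 measured members was 7.36 ± 0.14 (SD, n = 7) with cord plasma and 7.16 ± 0.07 (SD, n = 7) with PBS, a difference of 0.20. An exact two-sided permutation test of these array means gave p = 0.00233, or 0.00932 after adjustment over the 4 planned tests of this list, and 5 of the 7 cord plasma arrays lay above every PBS array. Adjusted over the 30 lists the methods differed: camera gave an adjusted p of 1.51e-05 with a preset correlation and 0.788 with an estimated one, fry 0.363, and the exact permutation p adjusted to 0.0699. Of the members, 26 were above 0 and 5 below. Adjusted over the list alone, 5 members rose: Npas4, an activity-dependent transcription factor, by 0.89 (SE 0.29), Fos by 0.67 (SE 0.21), the phosphatase gene Dusp1 by 0.52 (SE 0.16), Junb by 0.44 (SE 0.12) and Btg2 by 0.34 (SE 0.11). Over all genes tested none of them passed in limma, with an adjusted p of 0.348 for Fos. Other members were Nr4a1 at 0.50 (SE 0.20), Arc, a regulator of synaptic strength, at 0.39 (SE 0.26) and Egr1 at 0.33 (SE 0.21). The cortex markers described with young plasma were 0.26 (SE 0.18) for Lamp5 and 0.32 (SE 0.15) for Rspo1 here, and 0.13 and 0.20 without cord plasma replicate 7.

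**Figure D1:**
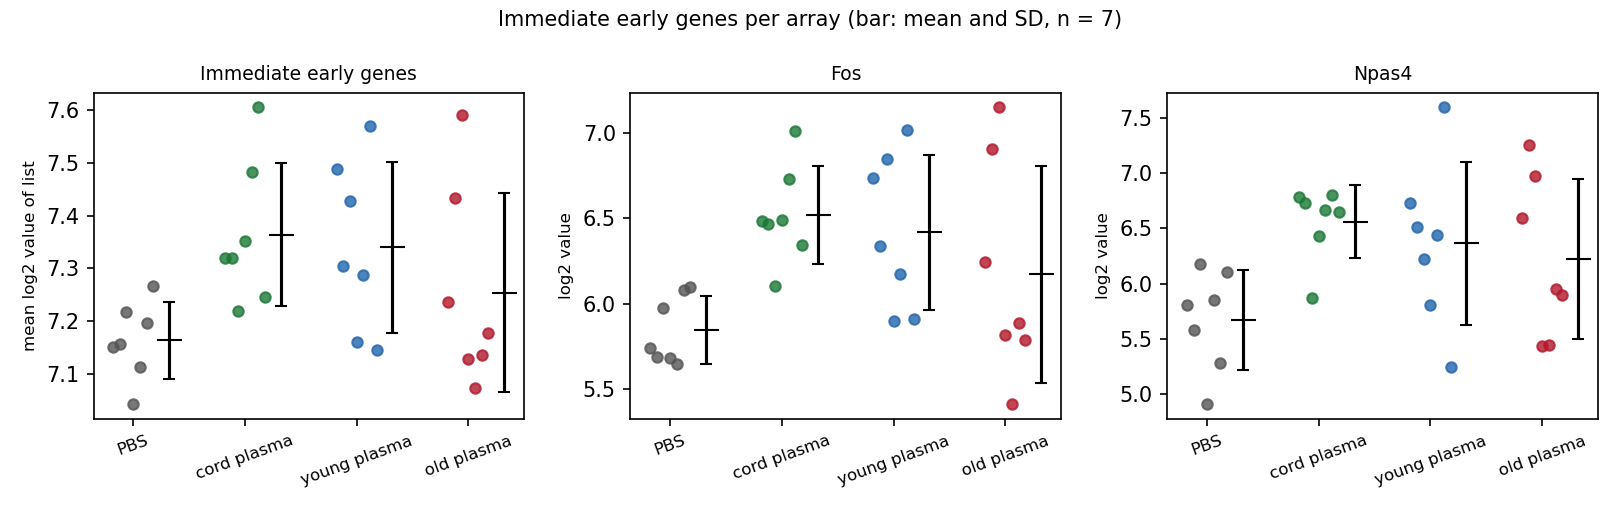
Immediate early genes on each array. The vertical axes give the mean log2 value over the list, and the log2 values of Fos and Npas4; each point is 1 array, and the bar beside each group is its mean and SD (n = 7). The list mean was 7.36 with cord plasma and 7.16 with PBS.

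No single gene passed an adjusted p of 0.05 in limma for cord plasma against PBS, where the smallest adjusted p was 0.224. At an unadjusted p under 0.05 limma counted 1380 genes, 783 above and 597 below 0, where 789 would come by chance. The authors' deposited table held 2169 of 23410 rows under that threshold, 1 of which stayed under 0.05 after Benjamini-Hochberg adjustment here. The smallest unadjusted p values above 0 included Jade1 at 0.24 (SE 0.05), Dact3 at 0.24 (SE 0.06) and Ctdsp1 at 0.31 (SE 0.07), and those below 0 Fam110a at -0.31 (SE 0.06), Olfr596 at -0.57 (SE 0.12) and Crygn at -0.28 (SE 0.06). Genes often followed in studies of brain ageing did not pass: Bdnf 0.09 (SE 0.07), Camk2a 0.03 (SE 0.03), Timp2 -0.14 (SE 0.12) or -0.25 without PBS replicate 1, the new-neuron marker Dcx -0.01 (SE 0.12), the astrocyte gene Gfap 0.03 (SE 0.06), the microglial gene Aif1 -0.01 (SE 0.05) and B2m, a subunit of antigen-presenting molecules, -0.0033 (SE 0.11), or 0.15 without PBS replicate 4. Csf2 fell under the filter on dim rows. Of the 30 gene lists, camera with a preset correlation called 6, 1 up and 5 down, and none with an estimated correlation, where the smallest adjusted p was 0.788. Centring each array on its median moved the share of genes above 0 among those with an unadjusted p under 0.05 from 56.7% to 81.3%.

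Young plasma was compared with PBS next. Circadian clock genes rose as a group. Their mean log2 value over 19 measured members was 8.20 ± 0.07 (SD, n = 7) with young plasma and 8.04 ± 0.04 (SD, n = 7) with PBS, a difference of 0.15, and each of the 7 young plasma arrays lay above every PBS array. The exact permutation test gave p = 0.000583, the smallest it can give, and 0.0175 after adjustment over the 30 lists; this test of every list was chosen after the data had been seen. Adjusted over the list alone, 5 of its members rose, among them Per1 at 0.47 (SE 0.11), the repressor gene Nr1d1 at 0.33 (SE 0.07), Bhlhe40 at 0.22 (SE 0.05) and Arntl, a core clock activator, at 0.19 (SE 0.04). With an estimated correlation camera gave this list an adjusted p = 0.129. Markers of the cortex and striatum beside the hippocampus moved with it: 5 of 19 rose and 2 fell, adjusted over the list alone, and Rspo1 was 0.63 (SE 0.15), Lamp5 0.54 (SE 0.18), Cux2 0.41 (SE 0.14) and Tbr1 0.36 (SE 0.13). Their list mean differed by 0.17, with an exact permutation p of 0.00350 and 0.0524 after adjustment over the 30 lists.

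**Figure D2:**
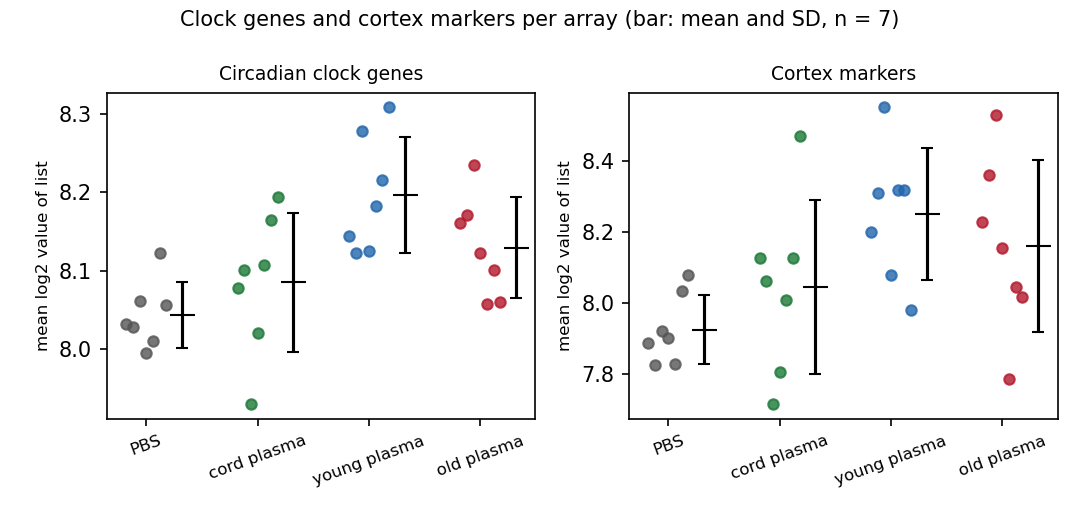
Circadian clock genes and cortex markers on each array. The vertical axes give the mean log2 value over the clock list and over 9 cortex markers; each point is 1 array, and the bar beside each group is its mean and SD (n = 7). The cortex markers averaged 8.25 with young plasma, 8.16 with old plasma, 8.04 with cord plasma and 7.92 with PBS.

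The immediate early genes differed by 0.18 between young plasma and PBS, with an exact permutation p of 0.0245 and 0.0490 after adjustment over the 4 planned tests. This lay just under the threshold and was not stable: the adjusted p was at or above 0.05 in 11 of 14 leave-outs of single arrays, all but those of PBS replicate 7 and young plasma replicates 4 and 7, and reached 0.103 without PBS replicate 4. Adjusted over the list alone, 4 members rose and 1 fell. Jun fell by 0.33 (SE 0.08), while Per1, Dusp1 at 0.47 (SE 0.16), Junb at 0.35 (SE 0.12) and Klf2 at 0.23 (SE 0.07) rose. Members that did not pass included Npas4 at 0.69 (SE 0.29), Fos at 0.57 (SE 0.21), Egr1 at 0.40 (SE 0.21) and Btg2 at 0.02 (SE 0.11). Arc was 0.07 (SE 0.26), and 0.40 without young plasma replicate 7. Genes of presynaptic vesicle release differed by 0.08 in their list mean, with an exact permutation p of 0.00583 and 0.0583 over the 30 lists. Values were 0.27 (SE 0.08) for Syn3, 0.28 (SE 0.11) for Stx1a and 0.07 (SE 0.03) for Snap25, a core protein of vesicle fusion. In limma no gene passed, with a smallest adjusted p of 0.108, and 1764 genes had an unadjusted p under 0.05. Among the smallest unadjusted p were Psmb11 at 0.32 (SE 0.06), Mansc1 at 0.27 (SE 0.05) and Abca8a at -0.37 (SE 0.08). The authors' deposited table held 1910 rows under an unadjusted 0.05 and 0 after adjustment here. Camera called 10 lists with the preset correlation and none with an estimated one. The glucocorticoid-responsive list was among them, and its call ended without young plasma replicate 7, where the adjusted p was 0.737; with an estimated correlation the list had an adjusted p = 0.806.

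Old plasma was compared with PBS as the third treatment. Genes of inflammation, complement and antigen presentation had a list mean 0.13 lower with old plasma, 6.17 ± 0.04 (SD, n = 7) against 6.30 ± 0.14 (SD, n = 7), and 21 of 23 members were below 0. The methods differed on this list. The planned camera test with the preset correlation called it down, with an adjusted p of 0.000544, or 0.0550 without PBS replicate 4, while an estimated correlation gave an adjusted p of 0.320. The exact permutation test, chosen after the data had been seen, gave p = 0.00233, and 0.0699 over the 30 lists. Neutrophil and blood monocyte markers were lower beside it, with a list mean of -0.17 (exact permutation p 0.0326, 0.195 over the 30 lists), and camera gave them an adjusted p of 0.00499 with the preset correlation and 0.320 with an estimated one. The list mean of these markers was also below PBS with cord plasma, at -0.13, and with young plasma, at -0.11. With old plasma, values were -0.35 (SE 0.11) for the acute-phase gene Saa3, -0.18 (SE 0.10) for Ccl2 and -0.21 (SE 0.11) for H2-Ab1, which was -0.13 without PBS replicate 6. Each of these genes was dim, with single arrays on both sides of the filter value of 4.68. PBS replicate 4 stood apart in the inflammation list, whose difference without that array was -0.08. Without it the neutrophil and blood monocyte markers differed by -0.11, and camera with the preset correlation gave them an adjusted p of 0.0624. The clock list differed by 0.09 (exact permutation p 0.0128, 0.192 over the 30 lists) and the immediate early genes by 0.09 (exact permutation p 0.296), or 0.03 without old plasma replicate 3. Among the immediate early genes Npas4 was 0.55 (SE 0.29), Fos 0.33 (SE 0.21), Egr1 0.33 (SE 0.21), Junb 0.13 (SE 0.12) and Btg2 0.05 (SE 0.11). The presynaptic list differed by 0.07 (exact permutation p 0.0198, 0.195 over the 30 lists); camera gave it an adjusted p of 0.000801 with the preset correlation and 0.320 with an estimated one, and fry 0.0468. Its member Syn3 had a value of 0.28 (SE 0.08). As with young plasma, cortex markers lay higher beside these lists: the list of cortex and striatum differed by 0.11 (exact permutation p 0.0495, 0.212 over the 30 lists), with Lamp5 at 0.48 (SE 0.18) and Rspo1 at 0.47 (SE 0.15). The smallest p of single genes belonged to Adap1 at 0.25 (SE 0.04) and 1810008I18Rik at -0.33 (SE 0.06), each with an adjusted p of 0.0515 in limma. Other genes with a small unadjusted p included Exoc3l at -0.31 (SE 0.06), Olfr596 at -0.57 (SE 0.12) and Nat8l, an enzyme of N-acetylaspartate synthesis, at 0.28 (SE 0.06). No gene passed, 1700 had an unadjusted p under 0.05, and the authors' deposited table held 2515 such rows and 0 after adjustment here. This count depended on scaling: with each array centred on its median 104 genes passed, 99 up and 5 down, and the share above 0 among genes with an unadjusted p under 0.05 moved from 61.5% to 89.0%. Array medians averaged 4.99 with old plasma and 5.03 with PBS. Camera called 7 lists with the preset correlation and none with an estimated one.

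The plasma groups were compared with each other to ask whether donor age mattered. Cord plasma also differed in its source, umbilical cord blood, so its comparisons cannot separate donor age from source. Cord plasma against old plasma gave no gene in limma, a smallest adjusted p of 0.999 and 663 genes with an unadjusted p under 0.05, fewer than the 789 that chance would give. The immediate early genes differed by 0.11 between cord and old plasma (exact permutation p 0.233, 0.296 over the 4 planned tests), so the difference between their responses was within the spread of the arrays. It was 0.17 without old plasma replicate 3 and 0.07 without cord plasma replicate 6. Members had values of 0.31 (SE 0.12) for Junb, 0.29 (SE 0.11) for Btg2 and 0.24 (SE 0.09) for Sik1. Fos was 0.35 (SE 0.21), Npas4 0.34 (SE 0.29) and Egr1 0.0031 (SE 0.21). Genes with the smallest unadjusted p included the small nucleolar RNA Snord53 at 0.42 (SE 0.09), Exoc3l4 at 0.25 (SE 0.06) and Hif3a at -0.33 (SE 0.09). Cplx1 had a value of -0.17 (SE 0.06) and Vamp2 of -0.10 (SE 0.04), and neither passed. Centring moved the share above 0 from 44.6% to 24.1%. Young against old plasma gave 1 gene, 1810008I18Rik, which was higher with young plasma by 0.41 (SE 0.06, limma adjusted p 0.00440), and 1031 genes with an unadjusted p under 0.05. That gene was dim, with a mean log2 value of 4.80, and its adjusted p was 0.0605 after renewed quantile normalization, 0.0544 after centring and 0.143 in a fit on these 14 arrays. The inflammation list differed by 0.10 between young and old plasma (exact permutation p 0.0437, 0.787 over the 30 lists), and camera gave it an adjusted p of 0.000991 with the preset correlation and 0.992 with an estimated one. Centring moved the share above 0 from 49.9% to 9.93%. Cord against young plasma gave no gene, a smallest adjusted p of 0.550 and 1140 with an unadjusted p under 0.05, among them Duox1 at -0.34 (SE 0.07) and Jsrp1 at -0.24 (SE 0.05). The clock list differed by -0.11 (exact permutation p 0.0239, 0.463 over the 30 lists) and the dentate granule markers by 0.14 (exact permutation p 0.0309, 0.463 over the 30 lists), with Npy1r at 0.21 (SE 0.09), or 0.13 without young plasma replicate 7, and Dock10 at 0.20 (SE 0.09). Markers of cortex and striatum had the opposite direction to the dentate markers, with list means of 7.04 with cord and 7.15 with young plasma (exact permutation p 0.118). Centring moved the share above 0 from 55.1% to 85.4%. Camera with the preset correlation called 6, 4 and 7 lists in these 3 comparisons and none with an estimated correlation.

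The mean of the 3 plasma groups was compared with PBS to find what the treatments shared. In limma 3 genes passed. Mansc1 was higher by 0.24 (SE 0.04, adjusted p 0.0449), Adap1, a neuronal phosphoinositide-binding protein, by 0.20 (SE 0.04, adjusted p 0.0449), and the olfactory receptor gene Olfr596 fell by 0.52 (SE 0.10, adjusted p 0.0488). Olfr596 was dim, with a mean log2 value of 4.79 where the filter lay at 4.68, and its adjusted p was 0.0649 without a filter. Mansc1 and Adap1 did not pass without a filter either. With the cortex markers as a covariate, 3 of the single-gene results that had passed over all comparisons no longer did. At an unadjusted p under 0.05 there were 1951 genes, and 19 genes had an adjusted p under 0.10. The count rested on single arrays: leaving out 1 array moved it between 0 and 42, with 42 genes without PBS replicate 1 and 0 without PBS replicate 4. Centring gave 18 genes and moved the share above 0 from 60.9% to 82.1%. Camera called 10 lists with the preset correlation and none with an estimated one. Over the 4 groups, the F-test of limma passed 1 gene, 1810008I18Rik, with an adjusted p of 0.0136, and 1552 genes had an unadjusted p under 0.05. The authors' deposited table held 2232 such rows for its test over the 4 groups and 2 after adjustment here. Tuba1b, an alpha-tubulin gene, was 0.34 (SE 0.09), 0.37 (SE 0.09) and 0.38 (SE 0.09) above PBS with cord, young and old plasma, and Fam131b 0.11 (SE 0.05), 0.22 (SE 0.05) and 0.20 (SE 0.05).

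Fold changes over PBS were correlated across genes between treatments, with r = 0.566 for cord and young plasma, 0.656 for cord and old plasma and 0.608 for young and old plasma. Genes are not independent replicates, and the treatments share the PBS arrays. Unchanged groups simulated against shared controls gave a mean r of 0.504, 0.507 and 0.499 over 100 draws, with highest values of 0.754, 0.780 and 0.783. With the PBS arrays split into sets of 3 and 4, over 35 splits, the mean r was 0.144, 0.180 and 0.182. The covariance was 0.00500, 0.00542 and 0.00554. Simulated means were 0.00363, 0.00361 and 0.00361, with highest values of 0.00905, 0.00849 and 0.00893, so the observed values lay within the simulated range.

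Several arrays and tissue markers stood apart. PBS replicate 4 had an interferon list mean of 7.13, while the other PBS arrays lay between 5.62 and 5.82. In this array Irf7 was 8.67 and Oasl2 7.76. Camera called the interferon list down with each of the 3 plasma treatments at the preset correlation, with an adjusted p = 0.788, 0.806 and 0.711 for cord, young and old plasma with an estimated correlation. The difference of their mean from PBS was -0.16 with every array and 0.04 without this one. Markers of choroid plexus and ependyma, the lining of the ventricles, ran from 5.53 to 7.80 over the arrays and spread widely within each group, with means of 6.65 ± 0.85 (SD, n = 7) for PBS and 6.40 ± 0.91 (SD, n = 7) for cord plasma. Thalamus markers were highest on PBS replicate 6, at 7.74. The mean of 4 Y-linked genes was lower with plasma than with PBS, by 0.08, 0.14 and 0.13 with cord, young and old plasma (exact permutation p 0.00641, 0.00874 and 0.0192, not adjusted), and lay between 6.89 and 7.40 on every array.

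**Figure D3:**
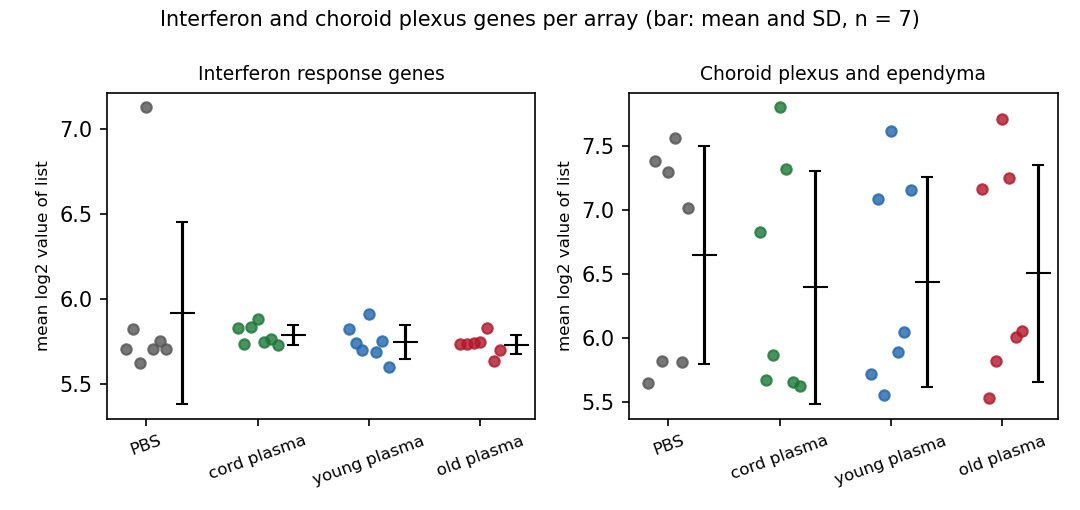
Interferon response genes and choroid plexus markers on each array. The vertical axes give the mean log2 value over each list; each point is 1 array, and the bar beside each group is its mean and SD (n = 7). PBS replicate 4 is the point at 7.13 among the interferon genes.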

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

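The tests of explanations in this part were chosen after the results had been seen, and the bound of the covariate tests was made stricter after a first outcome was known.

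Immediate early genes were higher with cord plasma than with PBS by 0.20 (SE 0.08 in a fit without covariates). A covariate for choroid plexus markers left a difference of 0.18 (SE 0.07), which argues against choroid plexus carried over with the hippocampus as the whole cause. The largest exact permutation p on leaving out 1 of the 14 arrays was 0.00641, without PBS replicate 4, so no single array carried the difference. With the cortex markers as a covariate the difference was 0.15 (SE 0.07). The bound set for these tests was met with the choroid plexus markers and missed with the cortex markers. Cortex carried over at dissection therefore cannot be told apart from the treatment. A response of hippocampal neurons to cord plasma may account for the difference and stays open as a hypothesis, as does handling before death, which the labels do not record.

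Clock genes were higher with young plasma than with PBS by 0.15 (SE 0.04). A different time of day of dissection would move genes in phase with Arntl and genes in antiphase in opposite directions. They were instead higher by 0.12 (SE 0.03, 5 genes) and 0.19 (SE 0.04, 9 genes), which argues against a shift of phase alone. Neither set was adjusted for the cortex markers, so a shift of phase beside a change of tissue content was not tested. No single array carried the difference, since the largest exact permutation p on leaving out 1 array was 0.00233. With the cortex markers as a covariate the difference was 0.0766 (SE 0.0325), so cortex carried over with the hippocampus cannot be told apart from the treatment, and Rorb belongs to both lists. An effect of young plasma on the clock may account for it and was not tested apart from tissue content.

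Interferon genes averaged 7.13 in PBS replicate 4, and the lower value of the plasma groups, -0.16, became 0.0365 without that array, so the difference rested on it. A first test of choroid plexus carried over with the hippocampus had a weak bound: the highest interferon mean among the 6 other arrays with as high a score was 5.91, above the highest array with a lower score, 5.84, by more than the SD of 0.073. A second test, added after that outcome, found PBS replicate 4 1.21 above those 6 arrays, which argues against choroid plexus in the amount they hold. Leukocyte markers had a median shift of 0.18 over 6 genes beside an SD of 0.08. Ptprc, which microglia also express, was 5.83 against 5.29 and Csf3r 6.19 against 6.01, each above every other array. Lyz2 was 6.64 against 6.29, Cxcr2 5.20 against 5.07, Elane 5.34 against 5.16 and Mpo 5.07 against 4.97, and none of them exceeded the highest other array. Neutrophil and blood monocyte markers averaged 5.90 on that array, microglia markers 7.31 and endothelial and pericyte markers 7.58, each above every other array. Red blood cell markers averaged 6.72, within the 6.56 to 6.75 of the other PBS arrays. Blood leukocytes in that sample may contribute, and they were not told apart from microglia. The design names no biological difference for 1 PBS array, and none was tested.

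Single arrays lay far from the other 6 of their group in 45 of 412 groups examined, 120 of them list means, where chance would give about 1 in 20, or 21. The other groups were genes given in the text, partly chosen after their values had been seen. Genes and lists also share members, so 45 beside 21 is no test of an excess over chance. In PBS replicate 4 the list means of inflammation genes, 6.61, and glucocorticoid-responsive genes, 7.74, stood apart, as did the interferon genes Irf7 at 8.67 and Oasl2 at 7.76, and B2m at 10.82, C1qb at 8.49, Ctss at 10.03 and Vamp2 at 9.65. In PBS replicate 6 presynaptic genes averaged 10.06 and thalamus markers 7.74, and H2-Ab1 was 5.49. In PBS replicate 1 neurogenesis genes averaged 6.39 and Timp2 was 9.24. In young plasma replicate 7 glucocorticoid-responsive genes averaged 8.43 and microglia markers 6.76, with Plin4 at 7.37, Klf9 at 10.81, Per1 at 10.30, Nr1d1 at 9.84, Arc at 7.59, Dcx at 5.43 and Aif1 at 5.52. Tuba1b was 7.21 in young plasma replicate 6.

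Among the cord plasma arrays, replicate 3 had means of 8.24 for ribosomal protein genes and 7.60 for cholesterol synthesis, with Npas4 at 5.87, Fam110a at 5.73 and Zmiz2 at 9.75. Replicate 7 had a mean of 7.74 for pyramidal neuron markers, with Rspo1 at 7.55, Lamp5 at 8.87 and Adap1 at 8.90. Replicate 4 had a mean of 7.43 for neurotrophins and growth factor signalling, and Klf9 was 10.04 in replicate 2. Among the old plasma arrays, replicate 1 had means of 7.84 for glucocorticoid-responsive genes and 7.68 for cholesterol synthesis, with Plin4 at 7.0. Replicate 2 had a mean of 8.14 for oligodendrocyte markers, with Dact3 at 8.28 and Vamp2 at 9.69. Replicate 3 had Nr4a1 at 9.64, Calb2 at 6.79 and Nat8l at 9.81, and replicate 6 had Abca8a at 5.57. The difference of 0.41 between young and old plasma in 1810008I18Rik is a test of the difference itself, described with its limits in the comparison of the plasma groups.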

How the results depend on the processing

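The choroid plexus and cortex covariates, the fit without PBS replicate 4 and young plasma replicate 7, the adjustment of the authors' deposited p-values and the exact permutation test of every list were chosen after the data had been seen. Cord plasma against PBS, cord against old plasma and cord against young plasma kept a count of 0 under the alternatives tried over the genes tested, other than the unadjusted threshold and leaving out single arrays; over all 23410 deposited rows the authors' p-values for cord plasma against PBS gave 1. Some list means turned in sign without single arrays, among them these: the interferon genes of any plasma against PBS went from -0.16 to 0.0365 without PBS replicate 4, and the glucocorticoid-responsive genes of young plasma against PBS from 0.10 to -0.03 without young plasma replicate 7. Where a count moved the cause was not tested unless stated.

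An unadjusted p under 0.05 in limma gave 1380 genes for cord plasma, 1764 for young plasma, 1700 for old plasma and 1951 for any plasma against PBS, 663 for cord against old, 1031 for young against old and 1140 for cord against young plasma, and 1552 over the 4 groups. An adjusted p under 0.10 gave 2 genes for old plasma and 19 for any plasma. Without a filter any plasma had 0 genes. A filter at the 50th percentile gave 1 for old plasma, 16 for any plasma, and 0 for young against old plasma and over the 4 groups, since 1810008I18Rik is dim. With every row tested, any plasma and the 4 groups had 0. Renewed quantile normalization gave 1 for young plasma, 5 for any plasma, and 0 for young against old plasma and over the groups. Centring on the median gave 104 for old plasma, 18 for any plasma, 0 for young against old plasma and over the groups, and 0.17 for the immediate early genes with young plasma, which no longer passed. A trended and robust fit gave 1 for old plasma, 13 for any plasma and 0 over the groups. Array weights gave 3 for old plasma and 11 for any plasma, with 6 gene lists for young plasma. Young against old plasma had 0 genes in a fit on those groups alone. A replicate block gave 1 for young plasma, and 0 for any plasma and over the groups. No label says whether the replicate numbers pair the arrays. The authors' deposited p-values gave 2 over the groups.

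With an estimated correlation camera called 0 lists in each of the 7 comparisons. The exact permutation test called 1 list for young plasma against PBS and 0 for cord and for old plasma against PBS and for the 3 pairs of plasma groups. The cortex covariate left 4 lists for cord against young plasma and 5 for any plasma. Over the 7 comparisons, 26 of the 50 list calls no longer passed with that covariate and 24 did. With it, 3 results of single genes that had passed no longer did. Without PBS replicate 4 and young plasma replicate 7, old plasma had 1 gene and any plasma 0, and the lists numbered 3 for cord plasma, 4 for old plasma and 6 for any plasma. With the PBS arrays split between the comparisons, the correlations of fold changes were 0.144, 0.180 and 0.182.

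Leaving out each array in turn gave 0 to 42 genes for any plasma, 0 to 10 for old plasma, 0 to 1 for cord plasma, for young plasma and over the groups, 1 to 1 for young against old plasma and 0 to 0 for cord against old and cord against young plasma. For any plasma the count was 42 without PBS replicate 1, 11 without PBS replicate 5, 6 without young plasma replicate 7 or old plasma replicate 5, 5 without young plasma replicate 1 or old plasma replicate 6, 1 without cord plasma replicate 6 or old plasma replicate 2, and 0 without PBS replicates 2, 3, 4, 6 or 7, cord plasma replicates 1, 2, 4 or 5, young plasma replicates 3, 4, 5 or 6, or old plasma replicates 1, 4 or 7. For old plasma it was 10 without PBS replicate 5, 4 without PBS replicate 1, 3 without young plasma replicate 7 or old plasma replicate 5, 2 without young plasma replicate 3 or old plasma replicate 6, and 1 without PBS replicate 4 or cord plasma replicate 7. Cord plasma had 1 without PBS replicate 1 or 5, young plasma 1 without PBS replicate 6 or old plasma replicate 2, and the 4 groups 0 without old plasma replicates 1, 2, 3 or 4. The lists numbered 5 to 12 for any plasma, 1 to 8 for cord plasma, 7 to 12 for young plasma and 4 to 11 for old plasma against PBS, 4 to 11 for cord against old, 2 to 6 for young against old and 5 to 9 for cord against young plasma. The immediate early genes differed by 0.16 to 0.22 with cord plasma, 0.14 to 0.21 with young plasma and 0.03 to 0.12 with old plasma against PBS, and by 0.07 to 0.17 between cord and old plasma. Signal over background, which the files do not give, limits the dim genes.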

Other observations

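The gene groups of the first 2 paragraphs were chosen after their values had been seen; the splits of the arrays were planned, and for the lists of cord plasma against PBS and against old plasma their test was chosen after the result had been seen.

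Glucocorticoid-responsive genes, which follow stress hormones, were lower with cord plasma than with young plasma in 22 of 22 measured members, with a list mean of -0.19, which was -0.06 without young plasma replicate 7. The exact permutation p was 0.124, and camera gave an adjusted p of 7.26e-08 with the preset correlation and an adjusted p of 0.507 with an estimated one. Against old plasma the list mean was -0.11 and 19 of 22 members were below 0, with an exact permutation p of 0.0653, and the mean was -0.06 without old plasma replicate 1. Hif3a was -0.33 (SE 0.09) there.

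Beside the lower inflammation genes of old plasma, neutrophil and blood monocyte markers were below 0 in 9 of 9 measured members with old plasma against PBS, with a list mean of -0.17, an exact permutation p of 0.0326 and 0.195 after adjustment over the 30 lists. Without PBS replicate 4 the mean was -0.11, and the exact permutation p was at or above 0.05 in 10 of 14 leave-outs of single arrays. Cxcr2, a chemokine receptor of neutrophils, was -0.42 (SE 0.10) by its brighter row and -0.04 by its other row. The lower values were not particular to old plasma. The neutrophil and monocyte list mean was -0.13 with cord and -0.11 with young plasma against PBS, or -0.08 and -0.05 without PBS replicate 4. Camera with the preset correlation called it down in both. The inflammation list was -0.08 with cord plasma, also called, and -0.02 without that array. With young plasma it was -0.03 and not called. Meningeal and fibroblast markers were below 0 in 20 of 21 members with old plasma against PBS, with a list mean of -0.15 (exact permutation p 0.142).

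Other splits of the same arrays were compared with the real ones, 100 for each comparison and the real one included. Counts were taken one at a time, without adjustment for the 8 examined, so a low number of splits does not exclude chance. For young against old plasma 4 splits gave as many genes as the real 1, and the highest other count was 2. Only the real split reached the 3 genes of any plasma against PBS, and the highest other count was 2. The count of young against old plasma is a single dim gene, and it was 0 after renewed quantile normalization, after centring, with a filter at the 50th percentile and in a fit on those 14 arrays. Leaving out a single array brought the count of any plasma to 0 for 16 of the 28 arrays. Chance could not be excluded over the 4 groups either, where 9 splits gave as many as the real 1 and the highest other was 12. For cord, young and old plasma against PBS, cord against old plasma and cord against young plasma the real count was 0, which 100 of 100 splits reached, and the highest other counts were 67, 11, 187, 1 and 6. Counts of 67, 187 and 11 from other splits point to a structure among the arrays, and what forms it was not tested.

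For the gene lists chance could not be excluded in any of the 7 comparisons. The splits with as many lists numbered 76 for cord plasma, 26 for young plasma, 71 for old plasma and 26 for any plasma against PBS, 53 for cord against old, 83 for young against old and 46 for cord against young plasma. The real counts were 6, 10, 7, 10, 6, 4 and 7 in that order, and the highest of the other splits 18, 13, 20, 15, 13, 13 and 13.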
